A study of Mus musculus with 8 samples.

How the data were processed

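Total RNA from Csk-deficient mouse embryonic fibroblasts was profiled on 8 one-colour (Cy3) Agilent miRNA arrays of design 031184, 2 per time of c-Src induction. Per the labels' protocols, 100 ng of RNA was dephosphorylated and labelled for each array. The deposited scanner files hold spot intensities made with Agilent Feature Extraction; its version is 10.7.3.1 per the submitters' processing notes and 10.5.1.1 per the file headers. Per the file headers, positions refer to mm9. The processed intensity in the deposited files is background-subtracted and not scaled between arrays, as checked on the values. The authors' value table holds the same processed intensity per spot, within 0.49%, on a linear scale, without centring or normalization, so neither its scale nor its centring stays unknown, and with 1 colour it has no direction. The medians of its columns for replicates 1 and 2 were 0.352 and 0.993 at 0 h, 0.547 and 0.709 at 6 h, 0.798 and 0.658 at 24 h, and 0.710 and 0.705 at 72 h. All 8 arrays lay on 1 slide and were scanned together, so slide and scan could not be used as a block. Each time filled 1 column of the slide and each replicate number 1 row, so time and slide column cannot be told apart.

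Each array held 45364 spots, of which 2164 control spots were left out, as were spots with an outlier flag. No spot was saturated, and 14.7% to 17.4% of miRNA spots were well above background. Processed intensities were scaled so that each array had the same 75th percentile over the 324 probes detected on all arrays. That percentile ranged from 414.6 to 570.9 units and averaged 546.4 at 0 h and 433.3 at 72 h. Values were then floored at 1 unit and taken to log2, and spots of a probe were averaged. A miRNA with several probes was read from the brightest, chosen over all 8 arrays. A probe counted as detected when at least 0.5 of its usable spots were well above background, and miRNAs detected on both arrays of at least 1 time were tested. This left 219 mouse miRNAs and 1 viral probe, 181 of them detected on all arrays. An "at least" fold sets the brighter group's mean against the dim group's mean of, per array, the higher of its signal and the lowest signal called well above background. Such a fold holds for the main setting only. The alternative background correction, normexp, gave a smaller change, or the opposite sign, for every called change with such a fold. Normexp was run with an offset of 50 units added before scaling, which by itself shrinks the log2 changes of dim probes. Scaling then multiplies the offset with the array, so a dim probe's sign can turn too. For dim probes normexp is therefore no independent test of a change.

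Times were compared with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), in one fit of all 8 arrays with eBayes and a variance trend, on 4 residual and 4.64 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 14 lists, and again with an estimated correlation and with fry, which tests whether a list's members move one way on balance. Of 208 fixed list members, 202 were matched to the array's names, 169 of them under an older name, and 6 were not matched. The design, lists, alternatives and rule for named miRNAs were set before the data were examined. By that rule the text names, per comparison with 0 h, the 10 largest rises and 10 largest falls past the threshold with both arrays outside the 0 h pair, or the 5 smallest p-values where fewer than 5 passed in a direction; 5 each for consecutive times; the miR-129 family; and up to 4 members per list with the smallest p. List members that did not pass were mostly given as counts, a choice made after their values were seen; where others are named, they were chosen after their values were seen.

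Replicate numbers were checked for pairing: the differences of replicate 1 and 2 correlated between times, with r from 0.445 to 0.535 over 6 pairs of times. The numbers match the rows of the slide, so a row effect and a pairing of samples cannot be told apart. These differences also ran with probe GC at each time (Pearson r from −0.162 at 6 h to −0.398 at 72 h). Replicates of a time correlated at 0.9974 to 0.9989 across miRNAs, and 26.5% to 38.6% of detected probes differed between them beyond the spread of their spots, so no array was a copy of another. The fit was tested on simulated data: in 20 data sets of 220 miRNAs for 72 against 0 h, 57% of miRNAs changed by 0.25 (log2), 95.2% of those changed by 0.5 and 100% of those changed by 1 were recovered, 5.08% of calls were false, and a list shifted by 0.3 was called in 100% of the data sets. The simulated noise was independent between miRNAs, normal with the fitted spread, and without the shared replicate difference seen above. These rates therefore hold under the assumptions of the fit and of the preset correlation, and do not check them. Alternatives covered scaling, background correction, floor, probe summary, filter, value table, replicate block, arrays in the fit, variance model and each array left out. Scaling on control probes, removal of a trend with probe GC content and removal of probes of 70% GC or more were added after seeing the data.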

Results

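MicroRNA levels were measured in mouse embryonic fibroblasts that lack Csk, the kinase that holds Src-family kinases in their inactive state. The cells carried a c-Src construct switched on by doxycycline at 1 µg/ml. RNA was taken at 0, 6, 24 and 72 h of induction, with 2 arrays per time and 8 arrays in all. The labels name no doxycycline-treated cells without the construct and no uninduced cells at later times. Effects of c-Src, of doxycycline and of time in culture therefore cannot be told apart. Each array carried probes for 1080 miRNAs, 1023 of them from mouse and 57 viral. On average 221.5 miRNAs per array were detected at 0 h, 213.5 at 6 h, 212 at 24 h and 189 at 72 h, and 220 entered the tests. The number of arrays limits the precision, and nothing in the labels says that the duplicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. miRNAs keep the names of the array design, in which an asterisk marks the passenger arm of a precursor, usually the less abundant one.

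The series' title names miR-129-3p, and its family was therefore read first on every array. The probe for miR-129-1-3p (ATACTTTTTGGGGTAAGGG, mm9 chromosome 6, 28972671 to 28972688) was dim throughout. Its log2 normalised signal was 3.25 ± 0.094 (SD, n = 2) at 0 h, 3.06 ± 0.14 at 6 h, 2.36 ± 0.016 at 24 h and 2.14 ± 0.14 at 72 h. The lowest signals that the scanner software placed well above background lay between 3.28 and 3.72, and the probe reached the detection rule, with 50% of its spots well above background, only on replicate 1 at 0 h. It was therefore outside the main test, and no fold is given because it was not well above background on both arrays of any time. When all 1080 miRNAs were tested without the filter, limma gave log2 changes of −0.19 at 6 h (SE 0.153, adjusted p = 0.999), −0.89 at 24 h (SE 0.153, adjusted p = 0.00124) and −1.12 at 72 h (SE 0.153, adjusted p = 4.52e-05), with both arrays below both 0 h arrays at each time. Adjusted over the list alone, the values at 24 and 72 h were 9.67e-05 and 7.03e-06. After the normexp background correction the difference was −0.013 at 6 h, −0.0061 at 24 h and 0.198 at 72 h. The normexp offset of 50 units exceeded the probe's signal, 10.9 units on replicate 1 at 0 h and 4.79 on replicate 1 at 72 h. Under normexp the median over all tested miRNAs was itself 0.167 at 72 h. That setting therefore cannot tell whether the probe fell, and a fall at signals this dim stays uncertain. The brightest probes of miR-129-2-3p and miR-129-5p had no spot well above background on any array, and their mean log2 signals at 0 h were 0.862 and 0.810.

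The comparison of 6 h with 0 h asks which miRNAs change first after induction. Passenger arms led the rises. miR-21*, from the precursor of the oncogenic miR-21, went from 4.46 ± 0.186 (SD, n = 2) to 5.64 ± 0.020, a 2.26-fold rise (adjusted p = 0.000423 by limma). miR-29b-1* rose by 0.57 (log2, SE 0.0905, adjusted p = 0.0186). miR-222* had a log2 difference of 0.76 (SE 0.135, adjusted p = 0.023), but was not well above background at 0 or 6 h, so no fold is given. The 4 falls were of other passenger arms, so all 7 calls were of passenger arms, against 39 of the 220 tested. miR-3102* fell by 0.65 (SE 0.125, adjusted p = 0.0276) and miR-211* fell by 0.59 (SE 0.126, adjusted p = 0.0399). miR-149* was at least 1.39-fold lower (adjusted p = 0.0356) and miR-135a-1* at least 1.17-fold lower (adjusted p = 0.023), both being not well above background at 6 h. Of the 4 falls, only miR-149* had a partner arm, miR-149, that was also tested. Whether the readings of miR-3102*, miR-211* and miR-135a-1* come from an expressed precursor was not checked. After normexp all 7 changes were smaller by over 1.5 times; miR-21* (0.44) and miR-3102* (−0.31) kept their calls, and the others lost theirs. The next by p did not pass the test: miR-31* had a log2 difference of 0.246 (adjusted p = 0.0829), miR-1904 of 0.195 (adjusted p = 0.202) and miR-494 of −0.261 (adjusted p = 0.0547).

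Among the fixed lists, the growth-promoting miRNAs of the STAT3 and AP-1 pathways were higher at 6 h by camera (adjusted p = 0.000463). That call was lost with an estimated correlation (adjusted p = 0.345), with which no list passed and 1 had an unadjusted p under 0.05, and with fry (adjusted p = 0.0502), which called the miR-29 family instead. Of the 10 members tested, 2 were called higher, miR-21* and miR-222*, and 8 did not pass. Of these 2, miR-222* was not well above background at 0 or 6 h. Adjusted over the list alone, 3 were called higher. The list's median change was 0.050 and its mean 0.231. Of the miR-29 family, 1 of 4 rose, also 1 adjusted over the list alone. In the list of the miR-143 and miR-145 cluster and in that of the Dlk1-Dio3 clusters, the 1 tested member of each (miR-143 with a log2 difference of 0.192, and miR-494) passed adjusted over the list alone and not over all miRNAs. No member of the other lists passed at 6 h either way.

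In all, 7 of the 220 tested miRNAs changed at 6 h, 3 higher and 4 lower, all with both arrays outside the range of the 0 h pair. Among all 220, 84 (38.2%) had such separated pairs, where chance gives 33.3% if the arrays are interchangeable. The difference between replicate numbers that the times share breaks that assumption, so 33.3% is not an exact chance level here. With the replicate number as a block, 16 changed, 6 higher and 10 lower, and miR-31* and miR-494 passed (adjusted p = 0.00279 and 0.0133). Quantile normalization gave 3 higher and 0 lower, no scaling 3 and 7, the total gene signal 3 and 1, and leaving out replicate 1 or replicate 2 at 0 h, or replicate 2 at 6 h, left 1 call each, and leaving out replicate 1 at 6 h left 4.

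By 24 h the changes had spread beyond passenger arms to miRNAs with brighter probes. miR-221, an X-linked miRNA that targets the cell cycle inhibitor p27, rose 1.71-fold from 9.06 ± 0.064 to 9.83 ± 0.047 (SD, n = 2; limma adjusted p = 1.43e-05). miR-29b rose 1.66-fold and miR-7a 1.65-fold, both with adjusted p = 1.43e-05. miR-21, read by a bright probe, rose 1.43-fold from 14.16 ± 0.065 to 14.68 ± 0.076 (adjusted p = 0.00259). The other leading rises were miR-29b-1* (log2 change 1.25), miR-21* (1.18), miR-146b (0.72), miR-31* (0.55) and miR-212-3p (0.49). miR-222* was at least 1.40-fold higher than at 0 h, where it was not well above background (1.20-fold after normexp). The falls were led by an X-linked cluster. miR-503 dropped from 9.05 ± 0.047 to 7.64 ± 0.239, a log2 change of −1.41 (adjusted p = 1.43e-05). miR-351 fell 2.15-fold, miR-322* fell by 0.71 and miR-351*, detected on 1 of the 2 arrays at 24 h, fell by 1.42. Outside the cluster, miR-3102* fell by 1.33, miR-211* fell by 0.93 and miR-2861 fell by 0.71. miR-149*, miR-3077* and miR-135a-1* were at least 1.31-fold, 1.35-fold and 1.1-fold lower, being not well above background at 24 h. The probes of miR-3102*, miR-211*, miR-149* and miR-135a-1* hold 76.9%, 69.2%, 90.9% and 76.9% GC. Changes at 24 h ran with probe GC over the 220 miRNAs (Pearson r = −0.277, Spearman r = −0.11). Probe GC may therefore account for part of these falls. After normexp 13 of these 20 changes were smaller by over 1.5 times, among them miR-29b-1* (0.39), miR-21* (0.49) and miR-351 (−0.53), and miR-149*, miR-3077* and miR-135a-1* lost their calls. miR-21 was at 0.23 under quantile normalization.

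The lists moved in both directions at 24 h. Of the growth-promoting STAT3 and AP-1 miRNAs, 8 of 10 rose, among them miR-31 (0.42) and miR-155 (0.32), and miR-181b fell by 0.19 (camera adjusted p = 0.000208; adjusted p = 0.182 with an estimated correlation). All 4 tested members of the miR-29 list rose (camera adjusted p = 2e-04, or 0.172 with an estimated correlation). They were miR-29a, miR-29b and miR-29c, regulators of collagen and DNA methyltransferase messages, and the passenger arm miR-29b-1*. Of the miR-17-92 and paralogous clusters, growth-promoting targets of MYC, 6 of 11 rose, led by miR-20b (0.33), miR-20a (0.31) and miR-18a (0.26). Camera gave this list an adjusted p of 0.00328, or 0.328 with an estimated correlation. In these clusters miR-18b and miR-363-3p were detected on 0 arrays, while miR-20b (mean log2 signal 9.31) moved much like its paralogue miR-20a. Cross-hybridisation of miR-20a to the miR-20b probe could therefore not be excluded. Of the miR-199 and miR-214 clusters of mesenchymal cells, 3 of 4 rose, with miR-199a-5p at 0.33 and miR-214 at 0.22 (camera adjusted p = 0.035; adjusted p = 0.416 with an estimated correlation). Of the X-linked cluster of miR-322, miR-503, miR-542 and miR-450, 9 of 10 fell (camera adjusted p = 0.000129; adjusted p = 0.328 with an estimated correlation). Of the miR-15/16 family, which restrains the cell cycle and shares miR-503 and miR-322 with that cluster, 4 of 7 fell, the others being miR-195 and miR-497 (camera adjusted p = 0.0069; adjusted p = 0.328 with an estimated correlation), while miR-15a, miR-15b and miR-16 had changes of −0.053, −0.063 and −0.065 that did not pass. Of the miR-30 family 4 of 7 fell, miR-30c by the most at −0.27 (camera adjusted p = 0.0303; adjusted p = 0.328 with an estimated correlation). All 3 miRNAs reported as lower in Src-transformed cells fell, miR-27b by 0.47, miR-542-3p by 0.41 and miR-99a by 0.21 (camera adjusted p = 0.0303; adjusted p = 0.321 with an estimated correlation). That list rests on earlier work on Src-transformed cells, which may include this line, so it is not independent evidence of its direction.

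With an estimated correlation no list passed at 24 h and 2 had an unadjusted p under 0.05; fry called 9. Of the 26 alternatives run with the preset correlation, 22 kept the call of the miR-17-92 list, 23 that of the miRNAs reported as lower in Src-transformed cells, 18 that of the miR-30 list and 13 that of the miR-199 and miR-214 list. The call of the miR-30 list was lost without replicate 1 at 24 h (adjusted p = 0.0554). That of the miR-199 and miR-214 list was lost without replicate 2 at 0 h (0.0815), replicate 1 at 24 h (0.11) or either replicate at 72 h (0.0526 without replicate 1). Of the 35 list members chosen by smallest p and called at 24 h, 10 had changes smaller by over 1.5 times after normexp and 5 under quantile normalization. In the other lists at 24 h, camera called no shift. In the miR-23/27/24 clusters 4 of 7 fell, miR-27b, miR-23b, miR-24 and miR-24-1*. In the miR-99/100, miR-125 and miR-10 families miR-125b-5p rose by 0.35, a change of 0 under quantile normalization, while miR-10b and miR-99a fell. let-7i was the 1 of 9 let-7 members that rose, and miR-494 the 1 tested member of the Dlk1-Dio3 clusters, which fell by 0.24. Adjusted over the list alone, the counts differed from those over all miRNAs at 24 h in the X-linked cluster, where 10 of 10 fell, and in the miR-23/27/24 clusters, where 1 rose and 4 fell.

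Altogether 87 miRNAs changed at 24 h, 41 higher and 46 lower. The split depended on the scaling, with 7 higher and 12 lower for the percentile over all probes, 13 and 36 with no scaling, 48 and 26 for the total gene signal, and 16 and 37 when scaled on control probes, an alternative chosen after seeing the data. Leaving out replicate 1 or replicate 2 at 0 h left 48 and 49 calls.

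At 72 h the cluster at mm9 chromosome X, 50401188 to 50407512, held the deepest falls. miR-503 fell 9.91-fold, from 9.05 ± 0.047 to 5.74 ± 0.043 (SD, n = 2; limma adjusted p = 2.77e-08), and the far brighter miR-322 fell 3.88-fold, from 12.23 ± 0.011 to 10.27 ± 0.081 (adjusted p = 6.03e-08). After normexp these falls were 4.80-fold and 3.81-fold. miR-351 fell by 2.77, miR-322* fell by 2.31, miR-542-3p fell by 1.42 and miR-542-5p fell by 1.39, with miR-351 and miR-542-5p detected on 1 of the 2 arrays at 72 h. After normexp these 4 stood at −0.82, −0.87, −0.49 and −0.14, the last no longer called. miR-351* was at least 2.31-fold lower, being not well above background at 72 h, but 1.17-fold lower after normexp. A second X-linked locus, which encodes miR-224 and miR-452 (69506378 to 69507636), followed: miR-224* and miR-452-3p were at least 1.30-fold and 1.04-fold lower, and miR-3077*, from elsewhere, at least 1.18-fold lower. The measured differences of these last 3 turned positive, to between 0.062 and 0.113, after normexp. On the other side, miR-221 rose 2.72-fold, miR-29b 2.67-fold, miR-222 2.31-fold and miR-29a 2.17-fold, with limma adjusted p of 5.27e-06 or lower. miR-7a rose by 1.00, miR-29b-1* by 1.05, miR-149 by 0.99, miR-582-5p by 0.97 and miR-21* by 0.97. miR-222* had a difference of 1.36 (adjusted p = 2.94e-05) with neither time well above background on any array. Of these 20 changes, 13 were smaller by over 1.5 times after normexp, among them miR-29b-1* (0.49), miR-149 (0.49), miR-582-5p (0.53) and miR-21* (0.51), and 4 with no scaling.

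**Figure D1:**
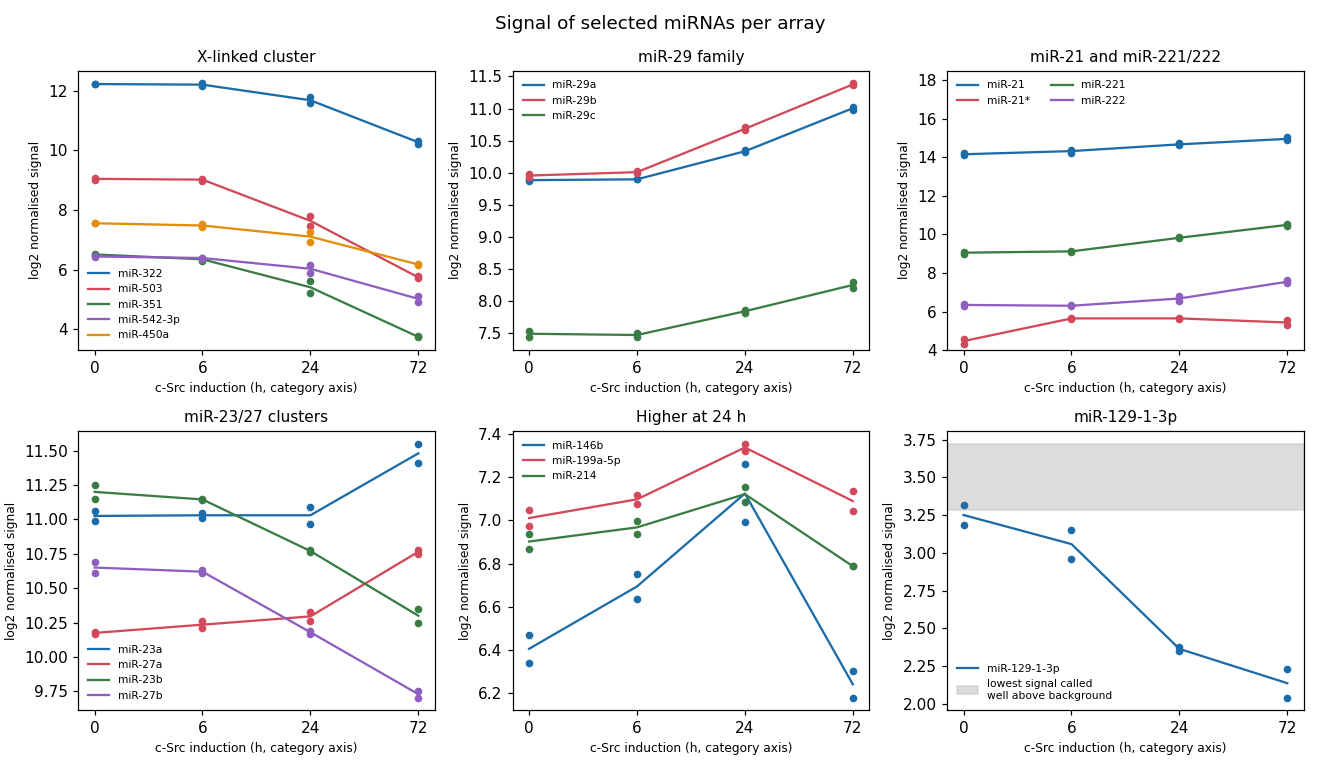
Log2 normalised signal (vertical axis) of selected miRNAs at 0, 6, 24 and 72 h of c-Src induction (horizontal axis, evenly spaced categories); each point is 1 array, lines join the means of the 2 arrays, and the grey band spans the lowest signals called well above background on the 8 arrays. miR-503 goes from 9.05 to 5.74, miR-29b from 9.96 to 11.37, and miR-129-1-3p from 3.25 to 2.14, below the band. The last fall is not seen after normexp, whose offset of 50 units exceeds that signal.

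The lists called at 72 h were the same in direction as at 24 h but for the miR-199 and miR-214 list and the miR-30 list, which did not pass (adjusted p = 0.27 and 0.0885). All 10 tested members of the X-linked cluster fell, with a median of −1.69 (camera adjusted p = 1.07e-06; adjusted p = 0.235 with an estimated correlation), and all 10 were lower under each of 6 scalings. After normexp, 1 of these 6, the cluster median was −0.65 and the smallest fall −0.092. Of the miR-15/16 family the same 4 members fell, miR-497 by 0.83 and miR-195 by 0.77 outside the cluster (camera adjusted p = 0.00369; adjusted p = 0.338 with an estimated correlation). All 4 miR-29 miRNAs rose, with a median of 1.08 (camera adjusted p = 0.00275; adjusted p = 0.229 with an estimated correlation). Of the growth-promoting STAT3 and AP-1 miRNAs 8 of 10 rose, with miR-21 at 0.80, miR-155 at 0.79 and miR-31 at 0.72, while miR-181b fell by 0.33 (camera adjusted p = 0.00308; adjusted p = 0.229 with an estimated correlation). The 8 included miR-222*, which was not well above background at 0 or 72 h. Of the miR-17-92 and paralogous clusters 9 of 11 rose, among them miR-92a (0.59), miR-20b (0.49), miR-18a (0.45) and miR-19a (0.43). Camera's adjusted p was 0.00275, or 0.338 with an estimated correlation. As at 24 h, the miR-20b probe may also read miR-20a. The 3 miRNAs reported as lower in Src-transformed cells fell, miR-542-3p by 1.42, miR-27b by 0.92 and miR-99a by 0.58 (camera adjusted p = 0.0118; adjusted p = 0.229 with an estimated correlation). With an estimated correlation no list passed and 3 had an unadjusted p under 0.05, and fry called 11. Of the 26 alternatives run with the preset correlation, 22 kept the call of the miR-17-92 list and 25 that of the last list. The median of every called list kept its sign under the other scalings, but not its size. That of the miR-17-92 list went from 0.41 to 0.20 for the percentile over all probes and to 0.070 with no scaling. With no scaling the STAT3 and AP-1 median went from 0.80 to 0.46, and that of the X-linked cluster from −1.69 to −2.025. The miR-15/16 median went from −0.77 to −0.38 after normexp. Of the 44 list members chosen by smallest p and called at 72 h, 13 had changes smaller by over 1.5 times after normexp, and with no scaling 18 were smaller and 12 larger by over 1.5 times.

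Several lists split at 72 h. In the miR-23/27/24 clusters, miR-27a rose by 0.59, miR-23a by 0.46 and miR-24-2* by 0.52, the arms of the cluster on chromosome 8, while miR-27b fell by 0.92, miR-23b by 0.90 and miR-24-1* by 0.56, those of the cluster on chromosome 13. The median of that list, −0.21, turned to 0.058 after normexp. The paralogues differ by few bases, so cross-hybridisation could not be excluded as a limit on the size of either change. In the miR-99/100, miR-125 and miR-10 families 2 rose and 3 fell, with miR-125b-5p at 0.73, miR-10b at −0.41 and miR-100 at −0.21, the last turning to 0.0987 when all probes were averaged. Of the let-7 family, growth-restraining regulators of RAS and MYC, 6 of 9 rose and let-7c fell by 0.18 (limma adjusted p = 0.00927). The list as a whole did not pass (camera adjusted p = 0.0788), and its median of 0.18 turned to −0.024 for the percentile over all probes and −0.154 with no scaling. let-7i rose by 0.58 and let-7d by 0.42, while let-7e (0.26) turned to −0.079 with no scaling and let-7g (0.18), the median member, turned likewise and was 0 under quantile normalization. Of the miR-30 family 4 of 7 fell, miR-30b by 0.33. In the miR-199 and miR-214 clusters miR-199a-3p fell by 0.42 and miR-199b* fell by 0.31. miR-210, induced in hypoxia, rose by 0.83 (adjusted p = 0.000262). Of 3 p53-induced miRNAs tested, miR-34b-5p rose by 0.46 and miR-192, detected on 1 of the 2 arrays at 72 h, fell by 0.26, the latter reversing to 0.205 after normexp. miR-494 of the Dlk1-Dio3 clusters fell by 0.41 and miR-466i-5p, 1 of 4 tested Sfmbt2 miRNAs, rose by 0.23, or −0.102 with no scaling. Adjusted over the list alone, each list's counts at 72 h equalled those over all miRNAs. Median and mean differed in sign in lists that camera did not call: the miR-23/27/24 list at 6 h (−0.025 and 0.0030), the neural list at 6 h (−0.029 and 0.0040), the miR-99/100, miR-125 and miR-10 list at 24 h (0.0025 and −0.032) and the Sfmbt2 list at 72 h (−0.034 and 0.0018).

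**Figure D2:**
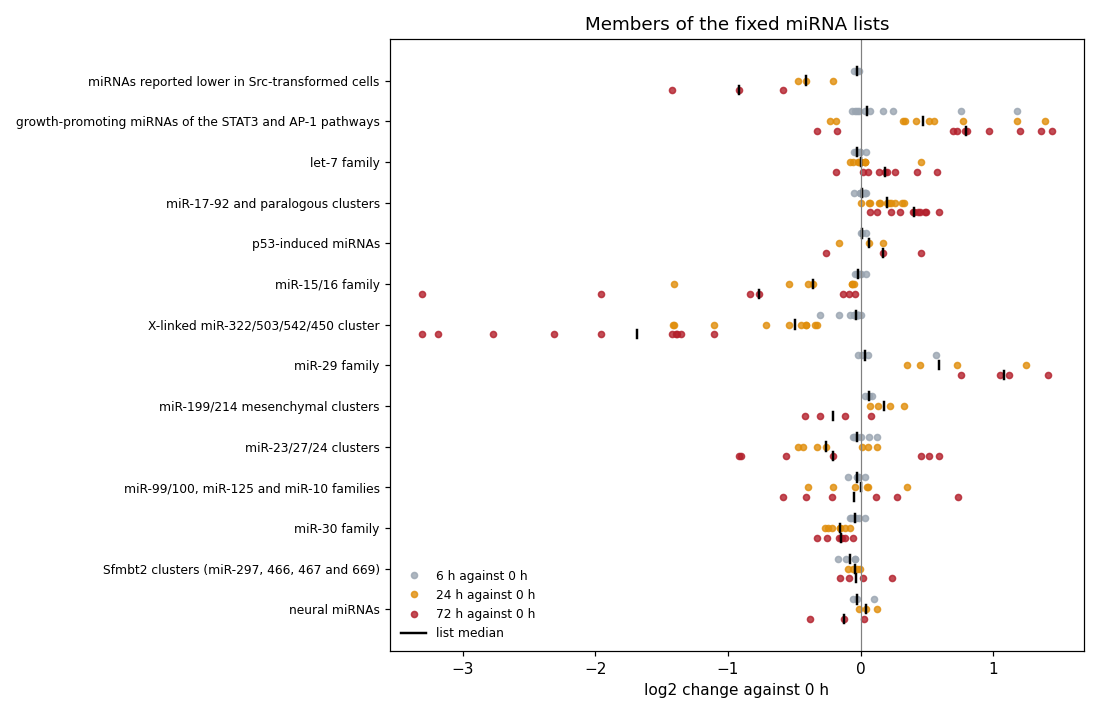
Log2 change against 0 h (horizontal axis) of each tested member (points, coloured by time) of the fixed lists with at least 3 tested members (vertical axis); black ticks mark list medians. At 72 h the 10 X-linked cluster members lie between −3.31 and −1.11 and the 4 miR-29 miRNAs between 0.76 and 1.42.

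miRNAs of other cell types were mostly not detected. None of the epithelial, haematopoietic, liver, embryonic stem cell or endothelial miRNAs was tested, and the brightest of each, miR-200b, miR-142-3p, miR-122, miR-294 and miR-126-3p, was detected on 0 arrays. Neural miR-218 (mean log2 signal 7.07) and muscle miR-206 (4.90) were detected on all 8 arrays. At 72 h, beside the lists above, miR-206 rose by 0.84 (adjusted p = 0.000898; 0.48 after normexp and 0.50 with no scaling) and miR-218 fell by 0.38 (adjusted p = 0.00028; −0.17 after normexp and −0.72 with no scaling).

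Altogether 133 miRNAs changed at 72 h, 67 higher and 66 lower. The split followed the scaling: 17 higher and 53 lower for the percentile over all probes, 21 and 114 with no scaling, 112 and 33 after normexp, and 32 and 82 when scaled on control probes. The median over all tested miRNAs shifted by −0.19, −0.32 and 0.17 under the first 3 of these, against 0.018 in the main setting, so small changes are relative to that shift.

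Consecutive times were also compared. From 6 to 24 h, 57 miRNAs changed, 28 higher and 29 lower, with miR-221, miR-29b, miR-29b-1* and miR-7a leading the rises and miR-503, miR-351, miR-3102* and miR-322* the falls. miR-222*, not well above background at 6 h, was at least 1.36-fold higher at 24 h (1.14-fold after normexp), and miR-351*, detected on 1 of the 2 arrays at 24 h, was lower. After normexp miR-222*, miR-351* and miR-3102* lost these calls. From 24 to 72 h, 90 changed, 51 higher and 39 lower, with miR-222, miR-582-5p, miR-29b, miR-221 and miR-29a ahead and the falls led by miR-503, miR-351 (detected on 1 of the 2 arrays at 72 h), miR-322* and miR-322. miR-351* was called lower too, but was not well above background at 72 h, so no size is given, and its difference turned positive after normexp. The splits for 6 to 24 h were 0 and 5 for the percentile over all probes, 6 and 17 with no scaling, 30 and 20 after normexp, and 6 and 35 on control probes; for 24 to 72 h they were 2 and 23, 6 and 71, 73 and 21, and 11 and 43, and 24 and 55 for the total gene signal. Leaving out replicate 1 or 2 at 6 h left 26 and 27 calls between 6 and 24 h. Over the whole course, limma's moderated F-test called 131 miRNAs.

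The same miRNAs recurred across times. All 7 called at 6 h were called in the same direction at 24 h, 3 higher and 4 lower, and likewise at 72 h. Independent lists would share 0.559 higher and 0.836 lower at 24 h, and 0.914 and 1.2 at 72 h. Of the 87 called at 24 h and 133 at 72 h, 33 were higher and 44 lower at both and 1 was called in opposite directions. Independent lists would share 12.5 and 13.8. Unchanged groups simulated against shared 0 h arrays in 100 data sets shared at most 1 call. As these groups held no real changes, almost no calls to share could arise, so this sets no chance level for the shared calls above. The log2 changes at 24 and 72 h correlated across miRNAs, which are not independent replicates, with r = 0.855 against 0.494 in the simulation, and their covariance was 0.217 against 0.00489. For 6 and 24 h the correlation was 0.742 against 0.494 and the covariance 0.0504 against 0.00474, and for 6 and 72 h the correlation was 0.485 against 0.5 and the covariance 0.0612 against 0.0049. With 1 of the 2 control arrays given to each comparison, an untested split, the covariance was 0.211 or 0.217 for 24 and 72 h, 0.0455 or 0.0482 for 6 and 24 h, and 0.0537 or 0.0617 for 6 and 72 h. The calls were not split, as 1 control array would remain to each, so part of the excess in shared calls may come from the shared 0 h arrays.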

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

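The tests of slide position, of noise in passenger probes, of arm order and of the X-linked cluster were chosen only after those results were seen, and the GC corrections were added after the data were seen.

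The effects at consecutive times differed, by limma's test of the difference, for these miRNAs with the largest changes. From 6 to 24 h the log2 differences were 0.71 for miR-221, 0.68 for miR-29b, 0.68 for miR-29b-1*, 0.65 for miR-7a and 0.63 for miR-222*, and −1.38 for miR-503, −1.11 for miR-351*, −0.94 for miR-351, −0.67 for miR-3102* and −0.67 for miR-322*. Of these, miR-222* was not well above background at 6 h, so its difference supports only at least 1.36-fold (1.14-fold after normexp), and miR-351* was detected on 1 of the 2 arrays at 24 h. From 24 to 72 h they were 0.87 for miR-222, 0.75 for miR-582-5p, 0.69 for miR-29b, 0.67 for miR-221 and 0.66 for miR-29a, and −1.90 for miR-503, −1.77 for miR-351*, −1.67 for miR-351, −1.60 for miR-322* and −1.42 for miR-322. miR-351* was not well above background at 72 h, so its last difference, which turned to 0.053 after normexp, gives no size. miR-351 was detected on 1 of the 2 arrays at 72 h.

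The X-linked cluster supplied most of those falls. The other 20 tested miRNAs encoded only on X, outside the locus of miR-224 and miR-452, had a median log2 change of 0.0787 at 72 h. The SE over these miRNAs was 0.164, and 8 were higher and 1 lower, which argues against loss or silencing of the whole chromosome. The 8 include miR-20b, whose probe may also read its paralogue miR-20a, encoded on chromosome 14. A drop in array signal by a common factor would move all miRNAs alike. The cluster median less that of all tested miRNAs was still −0.815 after normexp, with an SE over the cluster's members of 0.302. With either percentile scaling or none that difference was −1.708. Subtracting the median cancels a common factor, so those settings are not separate tests. A loss of signal confined to dim probes is not covered by this comparison. Both SEs describe spread over miRNAs, some of which share a locus and are not independent, and not spread over arrays. The size stays open: the cluster median was −0.648 after normexp and −1.69 in the main setting, so for the cluster as a whole the share of background treatment cannot be told apart. Normexp, whose offset by itself shrinks the changes of dim probes most, moved the bright miR-322 little, from 3.88-fold to 3.81-fold lower. The next brightest, miR-503, went from 9.91-fold to 4.80-fold lower. The dimmest moved most, with miR-450b-5p, miR-450b-3p, miR-542-5p and miR-351* at 1.07-fold to 1.17-fold lower after normexp. An effect of c-Src on this locus stays open and untested: no precursor or host transcript was measured, and time shares the slide column.

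The 4 falls called at 6 h, of which only miR-3102* kept its call after normexp, were dim probes of 69.2% to 90.9% GC. Changes at 6 h ran with probe GC over the tested miRNAs (Pearson r = −0.383). Replicate 1 minus 2 within a time did so too, from −0.162 at 6 h to −0.398 at 72 h. After each array's GC trend was removed, with the replicate block, all 4 kept adjusted p under 0.05 and their median went from −0.75 to −0.54. A linear GC trend is therefore not the whole cause but may be part of it. Only 19 tested probes had 70% GC or more, so the fitted line cannot exclude a GC effect that is not linear. Without the block, miR-149* (−0.84, SE 0.173, to −0.59, SE 0.156) and miR-135a-1* (−0.93, SE 0.167, to −0.76, SE 0.196) ended at adjusted p = 0.115, having shrunk. The other 88 tested miRNAs in the same signal range had a median of −0.0153 (SE over these miRNAs 0.0256), against a general loss of dim signal. Position on the slide cannot be told apart from time, since each time lies in 1 slide column; an effect of c-Src stays open.

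The 3 rises called at 6 h, of which only miR-21* kept its call after normexp, were all passenger arms, but so were the 4 falls (39 of 220 tested names), so the trait does not set the rises apart. All 3 partner arms, read by other probes, rose by 24 h. At 6 h they had not passed, with log2 differences of 0.17 for miR-21, 0.053 for miR-29b and −0.042 for miR-222. The later rise therefore does not test whether the 6 h readings were noise of dim probes, and miR-222* was not well above background at 0 or 6 h. All 3 rises kept adjusted p under 0.05 after the GC trend was removed with the replicate block. A hypothesis is that the dimmer arm shows new synthesis sooner: over the 15 arm pairs whose brighter arm rose by 72 h, the dimmer arm led at 6 h in 10, by 0.141 on average (median 0.0801), which chance could give (exact sign-flip p = 0.224, two-sided). The mean depended on few pairs: without the 3 rises that prompted the test it was −0.0175 (12 pairs, exact sign-flip p = 0.938), without the lowest pair, miR-149* (−0.90), 0.215 (14 pairs, exact p = 0.0168), and without all of these 0.0627 (11 pairs, exact p = 0.135). Such a lead is neither shown nor excluded, and slide column stays open here too.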

How the results depend on the processing

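The alternatives on control-probe scaling and probe GC content were chosen after seeing the data. Slide and scan blocks were not run, as all arrays share 1 slide and 1 scan. Floors of 0.1 and 5, the value table and the fit without a variance trend kept every count of changed miRNAs within 1.5 times. The cause of the differences below was not tested, except where fewer arrays or miRNAs entered.

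The count at 6 h, 7 in the main setting, was 3 for the percentile over all probes, 3 for quantile normalization, 2 for the mean of all probes, 4 for the total gene signal, 4 for miRNAs detected on all 8 arrays, 16 with the replicate block, 17 with only the 2 groups, 21 with the GC trend removed and the replicate block, and 4 without probes of 70% GC or more. Calls shared by 6 and 24 h, and by 6 and 72 h, followed it: 3, 3, 2, 4 and 4 under the first 5, 16 and 15 with the block, 21 and 18 with GC trend and block, and 4 without GC-rich probes. The percentile over all probes gave 19 at 24 h, 70 at 72 h, 5 from 6 to 24 h, 25 from 24 to 72 h, 56 at any time and 18 shared by 24 and 72 h. No scaling gave 49 at 24 h, 23 from 6 to 24 h and 45 shared by 24 and 72 h; control probes gave 53 at 24 h, 54 from 24 to 72 h and 50 shared; GC trend with the block gave 86 from 6 to 24 h. The block ended 0 calls and added 9, 22 and 24 at 6, 24 and 72 h, among them miR-31* (adjusted p = 0.00279), miR-494 (0.0133) and miR-146b (0.0106) at 6 h.

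Lists called were 0 at each time with an estimated correlation, 11 at 72 h with fry, 4 at 24 h for the percentile over all probes, no scaling and control probes, 2 at 6 h and 11 at 72 h with no filter (21 lists), and 2 at 6 h with the GC trend removed. The X-linked, miR-29, miR-15/16 and STAT3 and AP-1 lists kept their calls at 24 and 72 h under all 26 preset-correlation alternatives.

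For miR-129-1-3p, quantile normalization gave −0.057, −0.71 and −0.87 at 6, 24 and 72 h, normexp −0.013, −0.0061 and 0.198, a floor of 5 −0.71 and −0.64 at 24 and 72 h, and the mean of all probes −0.63 and −0.76; at 72 h the percentile over all probes gave −1.31, no scaling −1.43, a floor of 0.1 −1.30, the total gene signal −1.28 and control probes −1.28.

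With 1 array left out, the lone array is assumed to vary like the other groups. Counts then ranged from 1 to 9 at 6 h, 48 to 93 at 24 h, 116 to 140 at 72 h, 26 to 64 from 6 to 24 h, 75 to 88 from 24 to 72 h and 116 to 133 at any time; lists from 1 to 2, 6 to 8 and 6 to 6; shared calls from 1 to 9, 1 to 9 and 44 to 81; and miR-129-1-3p from −0.289 to −0.0968, −0.955 to −0.821 and −1.21 to −1.02.

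Single miRNAs reversed, or reached 0, as follows at 72 h unless stated: let-7g −0.024 (all probes), 0 (quantile) and −0.154 (no scaling); let-7e −0.079 and miR-466i-5p −0.102 (no scaling); miR-125b-5p 0 at 24 h (quantile); miR-3077* 0.071, miR-224* 0.062, miR-452-3p 0.113, miR-192 0.205 and miR-351* from 24 to 72 h 0.053 (normexp); miR-100 0.0987 (mean of probes); miR-30d 0.048 (GC trend, with and without the block). Of 128 named calls, 62 were lost for the percentile over all probes, 28 with no scaling and 21 after normexp. The lost calls had a median log2 signal of 8.96, 9.47 and 3.69, the others of 6.01, 6.72 and 7.86.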

Other observations

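Every value here was looked up after the data were seen. 6 miRNAs were called at 24 h and again, in the opposite direction, from 24 to 72 h. miR-146b, known to be induced by NF-κB, rose by 0.72 at 24 h (limma adjusted p = 0.000534) and then fell by 0.88 (adjusted p = 9.8e-05). With the replicate block it was also called at 6 h, higher by 0.29 (adjusted p = 0.0106), and at 72 h, lower, with a difference of −0.16 (adjusted p = 0.0191). miR-199a-5p, miR-214 and miR-199b*, from mesenchymal clusters, rose by 0.33, 0.22 and 0.14 and then fell by 0.25, 0.33 and 0.44. miR-362-3p and miR-532-3p, both X-linked, rose by 0.23 and 0.31 and then fell by 0.25 and 0.29.

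The 2 arms of miR-149 parted. miR-149 rose by 0.48 at 24 h and by 0.99 at 72 h (adjusted p = 2.34e-05), whereas miR-149* was at least 1.31-fold lower at 24 h and 1.1-fold lower at 72 h, where the difference turned to 0.107 after normexp. The dim miR-149* probe has 90.9% GC; its call at 6 h was lost after the GC trend was removed without the block (adjusted p = 0.115), and its calls at 6 and 24 h after normexp. At the locus of miR-224 and miR-452, miR-224 fell by 1.17 at 72 h (adjusted p = 8.21e-07) and miR-452-5p was at least 1.84-fold lower, a difference that turned to 0.020 after normexp. miR-148a fell by 0.64 at 72 h. miR-196a, not well above background at 72 h, was 1.43-fold lower as measured, a difference that turned to 0.136 after normexp. Its 72 h signal (3.85) lay above the lowest signals called well above background, so this fold is no lower bound. One viral probe, for a cytomegalovirus miRNA, was detected on all 8 arrays, with a mean log2 signal of 4.95 at 0 h and 4.98 at 72 h (adjusted p = 0.8).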
